A study of Homo sapiens with 30 samples.

How the data were processed

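RNA was sequenced from human blood monocytes that had been cultured alone or with platelets. Per the labels' protocols, monocytes were taken from fresh blood with CD14 beads and platelets from the same donor were washed and activated with collagen. The cells were mixed at 100 platelets per monocyte and harvested after 24 h or 6 days, when monocytes were selected again with beads against HLA-DR, a surface protein of antigen presenting cells. The sample titles call these times day 2 and day 7, and the times of the protocol are used throughout. The libraries were of stranded mRNA type, per the labels.

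The values used here are estimated counts for each annotated transcript, as whole numbers, in 1 table that the authors deposited. The genome build was GRCh38, per the submitters' processing notes. The aligner, the counting program and the annotation release were not given in the sources used here. The deposited table held 251550 transcripts of 60872 gene names, and 80.4% of the transcript identifiers were found in GENCODE release 29. It had 45 library columns, of which 30 matched the labels and were used, and 15 were not used. Estimated counts are apportioned among isoforms and near-identical genes, so values of FCGR3A (with FCGR3B), CCL3 and CCL4 (with their CCL3L and CCL4L copies), PF4 (with PF4V1) and HBA2 (with HBA1) are uncertain in how reads were divided.

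Transcript counts were summed per gene name. Y-linked genes, XIST, most HLA genes, genes with common whole-gene deletions and antigen receptor segments (1122 gene names) were left out of all tests but stayed in the library totals. Gene positions are those of GENCODE release 29 on GRCh38, counted from 1. Totals ranged from 10.5 to 24.3 M counts per library. Counting intervals and zero-count floors (3 counts over the group) cover counting error only, at 95%.

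The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM normalization, the default filter on low counts by group, and 1 fit over all 30 libraries in 4 groups. It covered 15576 genes with 26 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and standard errors were the log2 fold change divided by the square root of the F statistic. The contrasts were coculture against alone at each time, the difference between those effects, and 6 days against 24 h in each arm. Levels are CPM on library totals multiplied by TMM factors, or on plain library totals for genes too low to test and for platelet shares, given as mean ± SD.

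The 32 gene lists covered marker transcripts of other blood cells, monocyte and macrophage markers, and immune, lipid, redox, stress and quality groups. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, which compares a list with all other genes. The erythroid markers had 1 tested member and no list test. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were alternatives. The share of counts in platelet transcripts was compared with an exact two-sided permutation test in Python 3.11.15 (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9).

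These choices, the groups, the lists and the rule for named genes were fixed before the data were examined. The rule took, for each coculture comparison and for time in monocytes alone, the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with a mean of at least 2 CPM in 1 group. Coculture genes also had to move the same way in all but at most 1 donor pair. It added the 5 genes of smallest p in each direction for the difference between times, up to 4 members of smallest p from each list in each coculture comparison, and a panel of 21 genes whatever their result. Of the genes the rule took, 2 are left out of the text and its counts of named genes.

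Replicate numbers are those of the sample titles, and per the library names the 2 libraries with the same number at 1 time came from 1 donor. From number 6 on, the numbers do not match donors across the times. Replicate 6 at 24 h and replicate 7 at 6 days were 1 donor, as were replicate 7 at 24 h and replicate 8 at 6 days. The donor of replicate 6 at 6 days had no libraries at 24 h. There were 7 donor pairs at 24 h and 8 at 6 days, from 8 donors, 7 of whom had both times. Deviations of paired libraries from their group means correlated at 0.45 to 0.72 at 24 h and 0.10 to 0.75 at 6 days, and 7 of 7 and 6 of 8 pairs matched best with their own partner. A fit with the pair as a block was an alternative. Library names also fall into 2 sets, here called the first and the second name set, by a number whose meaning the labels do not state. The first set holds replicates 1 to 4 at each time, and the second holds the rest. Any batch behind these names is confounded with donors. No 2 libraries of a group agreed within sampling noise, with a smallest chi-square per gene of 17.4.

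The other alternatives were DESeq2 size factors and the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a fit of the compared groups alone, each replicate left out, each name set alone or as a term, and platelet genes removed. The pipeline was tested on simulated counts with 50 genes changed at each fold. In the 24 h comparison it recovered 8% of 1.5-fold, 68% of 2-fold, 96% of 4-fold and 100% of 8-fold changes with 2 false calls among 15576 genes. For 6 days these were 4%, 72%, 90% and 92% with 0 false calls, and for time in monocytes alone 16%, 54%, 92% and 96% with 7. Counts for these rates were drawn around means pooled over all libraries, with a reduced dispersion and a common spread between donor pairs. The simulated spread was therefore not that of each gene in the data, where recovery may differ. A simulated 1.3-fold change of the oxidative phosphorylation list was called at 24 h, and no other of the 31 lists was. Genes were simulated independently there, while the estimated correlation of that list in the data was 0.606. The simulation therefore cannot show how often lists of correlated genes are called falsely.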

Results

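RNA was sequenced from 30 libraries of human blood monocytes from 8 donors, cultured alone or with collagen-activated platelets of the same donor. The comparisons ask which monocyte transcripts change in coculture with platelets at 24 h and at 6 days. There were 7 libraries per arm at 24 h and 8 per arm at 6 days, which form 7 and 8 donor pairs. Total counts averaged 18.2 ± 1.13 M for monocytes alone and 19.0 ± 3.63 M for coculture at 24 h (mean ± SD, n = 7 each). They averaged 18.4 ± 3.51 M and 19.9 ± 1.94 M at 6 days (n = 8 each), and single libraries ranged from 10.5 to 24.3 M. The first principal component held 48.7% of the variance and placed every 24 h library below 0 and every 6-day library above 0. Levels are CPM on library totals scaled by TMM factors, or on plain totals for genes too low to test and for platelet shares, as mean ± SD over libraries, and log2 fold changes are coculture minus alone ± standard error. Adjusted p-values come from the quasi-likelihood test of edgeR unless another tool is named.

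At 24 h, coculture raised the genes for the monocyte-attracting chemokine CCL2, the plasminogen activator PLAU and the anti-inflammatory cytokine IL10. CCL2 (chromosome 17, 34255218 to 34257203, GRCh38) went from 15.9 ± 11.2 CPM alone to 274 ± 336 CPM in coculture (n = 7 each), a 17.3-fold rise (log2 4.11 ± 0.72, adjusted p = 0.00102, higher in 7 of 7 pairs). PLAU (chromosome 10, 73909177 to 73917497) rose 5.88-fold from 23.5 ± 10.8 to 138 ± 48.2 CPM (adjusted p = 7.38e-06, 7 of 7 pairs). IL10 rose 3.81-fold from 8.92 ± 4.24 to 34.0 ± 12 CPM (adjusted p = 0.000311, 7 of 7 pairs). Within the first and second name sets, the log2 rises were 2.27 and 5.96 for CCL2, 2.07 and 3.35 for PLAU, and 1.55 and 2.71 for IL10. The rise of CCL2 within the first set alone did not pass (adjusted p = 0.0872). Without replicate 7, CCL2 rose by 3.24 on the log2 scale.

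Across 15576 genes, 534 rose and 171 fell at 24 h, of which 230 and 41 changed at least 2-fold. With the donor pair as a block, 1211 rose and 712 fell, and 698 of the 705 genes were shared. The first name set alone called 78 genes and the second 281. The count was 278 without replicate 5, 384 without replicate 6 and 447 without replicate 7.

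The 10 largest rises at 24 h were DNAH17, CXCL5, ACKR3, PPBP, CCL2, WNT5A, LIF, TGM5, SLC16A10 and CABLES1, each higher in 7 of 7 pairs. DNAH17, which encodes a ciliary motor protein, went from 0.304 ± 0.141 to 21.4 ± 32.5 CPM (n = 7 each; log2 6.11 ± 0.88, adjusted p = 0.000158). CXCL5, a neutrophil-attracting chemokine gene, went from 2.27 ± 4.88 to 125 ± 313 CPM (log2 5.78 ± 1.39, adjusted p = 0.013), while the Wald test of DESeq2 gave it 1.39 (adjusted p = 0.483), limma-voom 3.01 (0.382) and a fit of only the 2 groups compared 5.76 (0.103). PPBP, a platelet chemokine gene, went from 0.221 ± 0.178 to 6.48 ± 12.6 CPM (log2 4.83 ± 1.05, adjusted p = 0.00857). Without replicate 7 the PPBP means were 0.173 ± 0.138 and 1.75 ± 1.31 CPM (n = 6 each), and it was too low to test without replicate 5, 6 or 7. CABLES1 went from 0.735 ± 0.468 to 10.3 ± 6.20 CPM (log2 3.81 ± 0.46, adjusted p = 1.78e-05). The log2 rises were 4.88 for ACKR3 (3.22 with the pair as a block and 3.24 with limma-voom), 4.09 for WNT5A, 4.07 for LIF, 3.86 for TGM5 and 3.85 for SLC16A10, with adjusted p from 0.000771 to 0.0127. Without replicate 7, the log2 rises were 5.15 for DNAH17, 3.96 for CXCL5, 2.86 for ACKR3 and 3.10 for LIF. SLC16A10 rose by 4.60 without replicate 4. TGM5 was not called without replicate 5 (3.17, adjusted p = 0.103).

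STEAP4, a metalloreductase gene, fell most at 24 h, from 12.3 ± 21.6 to 0.879 ± 0.632 CPM (n = 7 each; log2 −3.79 ± 0.75, adjusted p = 0.00282). CDKN2B, a cell cycle inhibitor gene, went from 21.7 ± 9.23 to 6.14 ± 1.77 CPM (log2 −1.82 ± 0.27, adjusted p = 0.000269). The other 8 of the 10 largest falls were ABCA6, FLT1, FCER2, ITGA11, HDAC9, ANGPT1, CLECL1 and SPARC, with log2 changes from −2.58 to −1.74 and adjusted p from 0.00556 to 0.0222. All 10 were lower in 7 of 7 pairs. With limma-voom FLT1 (−2.13, adjusted p = 0.231) and FCER2 (−2.01, 0.0793) were not called, nor was ITGA11 with only the 2 groups compared (0.0507). Without replicate 7, STEAP4 changed by −2.51. Omitting replicate 5 ended the calls of ITGA11 (adjusted p = 0.101), HDAC9 (0.0591), ANGPT1 (0.0816), CLECL1 (0.11) and SPARC (0.103). Omitting replicate 2 ended those of FCER2 (0.064) and ANGPT1 (0.065), and omitting replicate 6 those of FCER2 (0.061), CLECL1 (0.0639) and SPARC (0.0583). Omitting replicate 7 ended those of FCER2 (0.061), ANGPT1 (0.0682) and CLECL1 (0.0557).

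Genes of cholesterol efflux, which the sterol-sensing LXR receptors switch on, rose at 24 h. Of 14 tested, 12 rose and none fell, and 13 rose when adjusted over the list alone (median log2 1.17, adjusted p = 1.47e-16, 0.00116 with an estimated correlation). ABCG1, a sterol exporter gene (chromosome 21, 42199689 to 42297244), rose 5.12-fold from 6.51 ± 3.25 to 33.4 ± 18.1 CPM (n = 7 each, adjusted p = 0.00399, 7 of 7 pairs). APOE rose 3.36-fold (adjusted p = 0.00373), SCD 2.61-fold (0.00233) and APOC1 2.52-fold (0.0161), each in 7 of 7 pairs. APOC1 was not called without replicate 6 (log2 1.21, adjusted p = 0.0809). ABCA1, the main sterol exporter gene (chromosome 9, 104781002 to 104928237), rose 1.96-fold from 147 ± 40.4 to 288 ± 115 CPM (adjusted p = 0.0425). Its call ended on omitting any of replicates 1 to 7, with log2 rises of 0.84 to 1.06 and adjusted p of 0.059 to 0.13, and without the filter on low counts (0.0763). Mean rises of the list per pair were 1.08 ± 0.23 in the first name set (n = 4) and 1.27 ± 0.25 in the second (n = 3), and all 7 pairs were above 0. Genes of cholesterol synthesis did not pass singly at 24 h, since none of 21 was called by edgeR, DESeq2 or limma-voom and 2 were lower at an unadjusted p under 0.05. Their list was lower than other genes (median −0.161, adjusted p = 0.0158, 0.616 with an estimated correlation).

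Lysosome and phagocytosis genes were higher as a list too at 24 h. Of 22 tested, 10 rose and none fell, with 13 adjusted over the list alone (median log2 0.554, adjusted p = 4.17e-16, 0.00365 with an estimated correlation). The protease gene CTSD went from 1613 ± 424 to 3770 ± 1142 CPM (n = 7 each, adjusted p = 0.0003), CTSL rose 3.34-fold (0.000311), and MERTK, a receptor gene for dying cells, rose 4.19-fold (0.000389). ASAH1 rose 1.70-fold (0.00115), and all of these were higher in 7 of 7 pairs. Among 22 macrophage markers, 5 rose and none fell, with 6 adjusted over the list alone (adjusted p = 0.00129, 0.223 with an estimated correlation). With the pair as a block, 15 of the lysosome genes rose and none fell, and 9 of the macrophage markers rose and 1 fell. LGMN, a lysosomal protease gene among the markers, rose 5.56-fold from 196 ± 102 to 1091 ± 551 CPM (adjusted p = 0.00337).

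Genes that respond to TGF-beta, a cytokine that platelets store, rose at 24 h. Of 17 tested, 11 rose and none fell, with 13 adjusted over the list alone (median log2 0.692, adjusted p = 3.93e-15, 0.0237 with an estimated correlation). ID3 rose 4.84-fold from 8.48 ± 1.51 to 41.0 ± 23.8 CPM (n = 7 each, adjusted p = 0.000299), LTBP2 8.82-fold (0.000899) and PMEPA1 6.52-fold (0.00112), each in 7 of 7 pairs. Mean rises of the list per pair were 0.59 ± 0.16 in the first name set (n = 4) and 1.37 ± 0.21 in the second (n = 3), a difference with an exact permutation p of 0.0286, the smallest possible, and 0.177 when adjusted over 31 lists. Both sets were above 0 in every pair. Within the second set 7 of these genes rose and within the first 4.

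Among 17 matrix proteolysis genes 5 rose and none fell at 24 h, 5 when adjusted over the list alone (adjusted p = 6.1e-05, 0.186 with an estimated correlation), and MMP14 rose 3.93-fold (0.00164). With limma-voom 3 of the 17 rose. Of 16 chemokine genes 4 rose and none fell, also 4 adjusted over the list alone (adjusted p = 0.0208, 0.408 with an estimated correlation). They were CCL2, CXCL5, CXCL1 and CCL18, of which limma-voom called CCL2 alone, with CXCL5 at an adjusted p of 0.382, CXCL1 at 0.128 and CCL18 at 0.419. CXCL1 rose 10.1-fold (adjusted p = 0.0104; log2 2.14 with the pair as a block against 3.33) and was not called without replicate 7 (1.82, adjusted p = 0.0563) or with only the 2 groups compared (0.0584). CCL18 rose 6.52-fold (0.0252) and was not called without any of replicates 1, 3, 4, 5 or 6 (adjusted p from 0.0553 to 0.0901). Of 15 coagulation and fibrinolysis genes 3 rose and none fell, 3 when adjusted over the list alone (adjusted p = 0.0158, 0.223 with an estimated correlation). These were PLAU, its receptor gene PLAUR (2.95-fold, 0.00387) and PROCR (log2 3.11, adjusted p = 0.00601, and 2.38 without replicate 7). Of 25 genes of glycolysis and hypoxia 1 rose, VEGFA at 5.42-fold (0.000399), with 3 adjusted over the list alone and 4 under the pair block (list adjusted p = 0.00206, 0.513 with an estimated correlation).

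Ribosomal protein genes were slightly lower as a list at 24 h. Of 20, 5 fell and none rose, 18 fell when adjusted over the list alone and 15 with the pair as a block (median log2 −0.285, adjusted p = 2.75e-14, 0.218 with an estimated correlation). RPL32 dropped by 0.43 on the log2 scale (adjusted p = 0.00665) and RPL4 by 0.39 (0.0141), each in 7 of 7 pairs, and RPL4 was not called without replicate 6 (0.0507) or 7 (0.0628). In the same libraries the T and NK cell markers had a median of −0.66 and the B cell markers of −0.782. Those lists did not pass (adjusted p = 0.0508 and 0.0522) but passed with the pair as a block (0.0038 and 0.00061). None of 17 T and NK markers was called by edgeR, DESeq2 or limma-voom, none passed an unadjusted p under 0.05, and 1 was called with the pair as a block. Among 11 B cell markers, FCER2 fell with edgeR but not with limma-voom (adjusted p = 0.0793). Interferon-stimulated genes (adjusted p = 0.00046, 0.534 with an estimated correlation) and mitochondrially encoded genes (0.000354, 0.385) were lower as lists, with medians of −0.505 and −0.224. No gene of either was called by edgeR, DESeq2 or limma-voom, although 6 and 4 were lower at an unadjusted p under 0.05, and 2 mitochondrial genes fell with the pair as a block.

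The adhesion genes split at 24 h, with 4 higher and 2 lower of 20, or 7 and 2 adjusted over the list alone, and the list did not pass (adjusted p = 0.0928). F11R, an adhesion gene shared by platelets and white cells, rose 2.83-fold from 28.6 ± 8.07 to 80.8 ± 22.3 CPM (n = 7 each, adjusted p = 7.38e-06), and ITGAV rose 2.18-fold (0.00186). ITGAL, an integrin gene, went from 630 ± 200 to 294 ± 119 CPM (log2 −1.10, adjusted p = 0.00611). NF-kB target genes did not pass (adjusted p = 0.0507) but passed with the pair as a block (0.0115), and of 20 the gene IL1A rose (log2 2.09, adjusted p = 0.0309, 5 of 7 pairs). IL1A was not called without any of replicates 2, 3, 5, 6 or 7 (adjusted p from 0.0531 to 0.122), with limma-voom (0.136), without the filter on low counts (0.056) or with only the 2 groups compared (0.0892). The remaining lists that did not pass had adjusted p of 0.84 for platelet markers, 0.22 for neutrophil, 0.788 for dendritic cell and 0.253 for monocyte markers. They had 0.411 for antigen presentation, 0.0605 for inflammasome, 0.175 for alternative activation and 0.302 for complement genes. For metabolic and stress lists the values were 0.716 for NRF2 targets, 0.272 for reactive oxygen genes, 0.0507 for oxidative phosphorylation, 0.252 for lipid uptake, 0.759 for both ER stress and heat shock, and 0.301 for the cell cycle. The ER stress list had a median of 0.021, a mean of −0.165 and a downward test.

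Single genes in these lists still changed at 24 h. CDKN1C rose 4.70-fold (adjusted p = 0.00145), and GCLC, a glutathione synthesis gene, went from 156 ± 46.0 to 89.7 ± 14.8 CPM (n = 7 each, log2 −0.80, adjusted p = 0.00144, lower in 6 of 7 pairs). MAFG rose by 0.47 (0.00164). IFI30 rose by 0.63 (0.00943) and was not called without replicate 5 (0.0632) or with only the 2 groups compared (0.0522). C3 rose by 1.91 (0.0237) and was not called without replicate 5 (0.115), 6 (0.103) or 7 (0.0584), and DGAT2 by 2.22 (0.0167), not called without replicate 5 (0.0633), 6 (0.0731) or 7 (0.0817), with limma-voom (0.068) or with only the 2 groups compared (0.0545). FCGR3A, the CD16 gene of nonclassical monocytes, rose 3.24-fold (0.0172), with its call ending without replicate 5 (log2 1.59, 0.0818) or 6 (0.0537). Its reads cannot be divided with certainty from those of FCGR3B, which is on the neutrophil list, and 1 of the 10 neutrophil markers tested also rose. The rise of FCGR3A therefore cannot be assigned to nonclassical monocytes. The interferon-stimulated gene USP18 did not pass (−1.18, adjusted p = 0.132) and passed without replicate 4 (−1.79, 0.00896).

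Most of the inflammatory and redox genes in the fixed panel did not pass at 24 h. IL1B changed by 1.40 (adjusted p = 0.237), TNF by −0.31 (0.677), CXCL8 by 0.78 (0.585), F3 by −0.17 (0.947) and THBS1 by 0.14 (0.967). HMOX1 changed by 0.55 (0.32, and 0.0419 with only the 2 groups compared), NQO1 by 0.48 (0.556), CYBB by −0.12 (0.921) and TXNIP by −0.17 (0.809). SOD2 (0.75, adjusted p = 0.329) and MRC1 (1.11, 0.173) did not pass but passed with the pair as a block (0.52, 0.019 and 1.04, 0.0082). The surface marker genes CD14 (0.31, 0.67), CD36 (0.01, 0.991) and CD163 (0.66, 0.636) did not pass. HLA-DRA, whose product was used to select the cells before lysis, changed by −0.29 (adjusted p = 0.805). IL6 was too low to test, with 0.0532 CPM alone and 0.819 CPM in coculture. Cocultured replicate 7 held 132 of the 138 IL6 counts in coculture, 3 of 7 cocultured libraries had any, and without that replicate 2 counts were left alone and 6 in coculture.

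At 6 days, coculture lowered the genes of cholesterol synthesis and raised those of cholesterol efflux. FDFT1, which commits the pathway to sterols (chromosome 8, 11795573 to 11839309), went from 102 ± 31.4 to 44.9 ± 11.4 CPM (n = 8 each; log2 −1.18 ± 0.17, adjusted p = 0.000131, lower in 8 of 8 pairs). ABCG1 rose 10.3-fold from 4.33 ± 4.84 to 45.6 ± 23.3 CPM (log2 3.37 ± 0.48, adjusted p = 0.000131, 8 of 8 pairs). ABCA1 rose 2.38-fold from 101.3 ± 49.2 to 241 ± 111 CPM (adjusted p = 0.00315, 8 of 8 pairs). Of 21 synthesis genes 14 fell and none rose, with 19 adjusted over the list alone (median log2 −0.775, adjusted p = 1.37e-30, 0.0216 with an estimated correlation). CYP51A1 and MVD were among them (−1.20, adjusted p = 0.000279 and −0.91, 0.000242). Of 14 efflux genes 7 rose and none fell, with 11 adjusted over the list alone (median 0.898, adjusted p = 3.18e-11, 0.0197 with an estimated correlation), among them APOC1 (1.94, 0.000416) and MYLIP (0.96, 0.00243).

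Within the first and second name sets, FDFT1 changed by −1.26 and −1.07 at 6 days, and ABCG1 by 4.29 and 3.02. Neither passed within the second set alone (adjusted p = 0.297 and 0.27). Per pair, the synthesis list averaged −0.92 ± 0.42 in the first set and −0.98 ± 0.52 in the second (n = 4 each, exact permutation p = 0.829), and all 8 pairs were below 0. The efflux list averaged 0.94 ± 0.32 and 1.22 ± 0.19 (exact permutation p = 0.171), with all 8 pairs above 0.

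**Figure D1:**
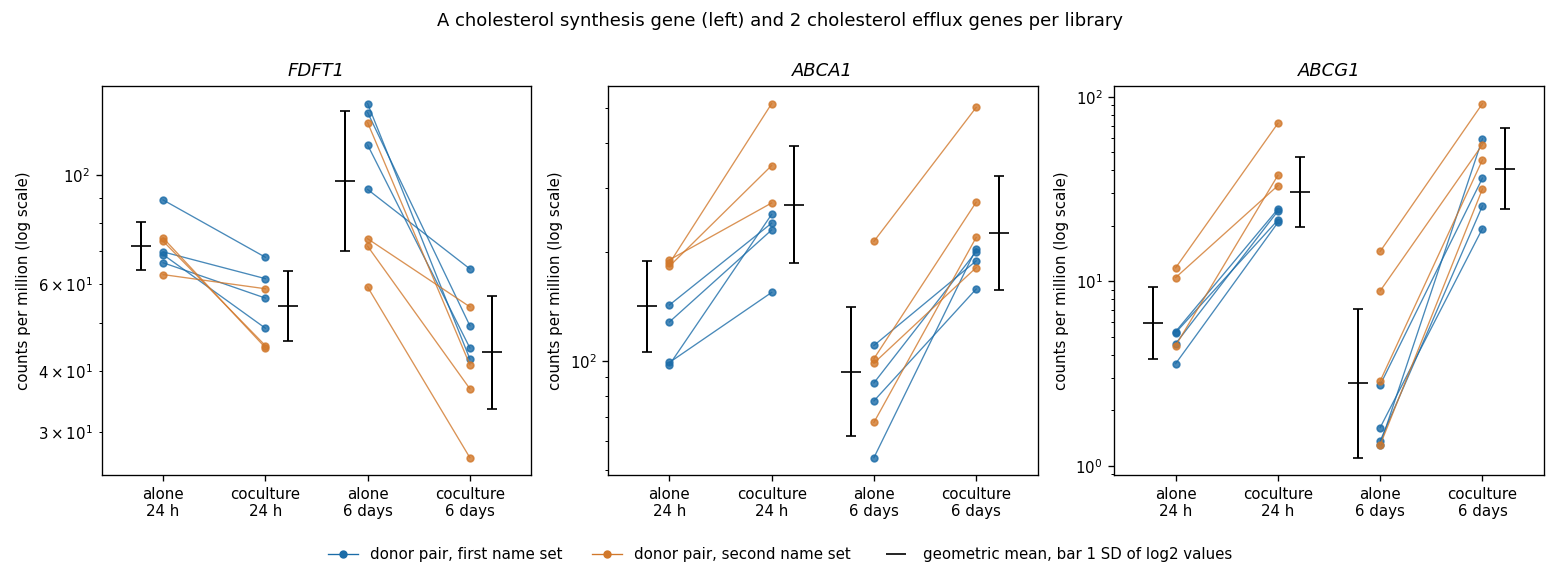
Levels of FDFT1, ABCA1 and ABCG1 in CPM on a log axis for each library at 24 h and 6 days, where lines join donor pairs, colours mark the name sets, and black marks show the geometric mean ± 1 SD of log2 values. At 6 days FDFT1 lay between 59.3 and 139.8 CPM in monocytes alone and between 26.7 and 64.5 CPM in coculture, and ABCG1 between 1.3 and 14.5 CPM and between 19.3 and 92.0 CPM.

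Cell division genes rose at 6 days. MKI67, the proliferation marker gene (chromosome 10, 128096659 to 128126385), went from 5.42 ± 4.71 to 68.6 ± 73.6 CPM (n = 8 each; log2 3.64 ± 0.65, adjusted p = 0.000991, higher in 8 of 8 pairs), a 12.5-fold rise. In the first set alone its log2 rise was 4.33 (adjusted p = 0.000134) and in the second 1.23 (0.794). Of 20 cell cycle genes 19 rose and none fell, with 20 adjusted over the list alone (median 2.99, adjusted p = 5.8e-19, 0.165 with an estimated correlation), including BIRC5 (3.48, 0.000624), CENPF (3.10, 0.000392) and RRM2 (3.89, 0.000991). Mean rises of the list per pair were 3.07 ± 0.68 in the first set and 0.82 ± 0.76 in the second (n = 4 each), a difference with an exact permutation p of 0.0286, the smallest possible, and 0.0985 when adjusted over 31 lists. With limma-voom 7 of the 20 rose, among them CENPF (2.39, adjusted p = 0.0292) but not MKI67 (2.78, 0.0677), BIRC5 (2.53, 0.0528) or RRM2 (2.90, 0.109). In the same libraries lymphocyte markers were lower, with medians of −1.25 for T and NK cells and −2.10 for B cells.

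**Figure D2:**
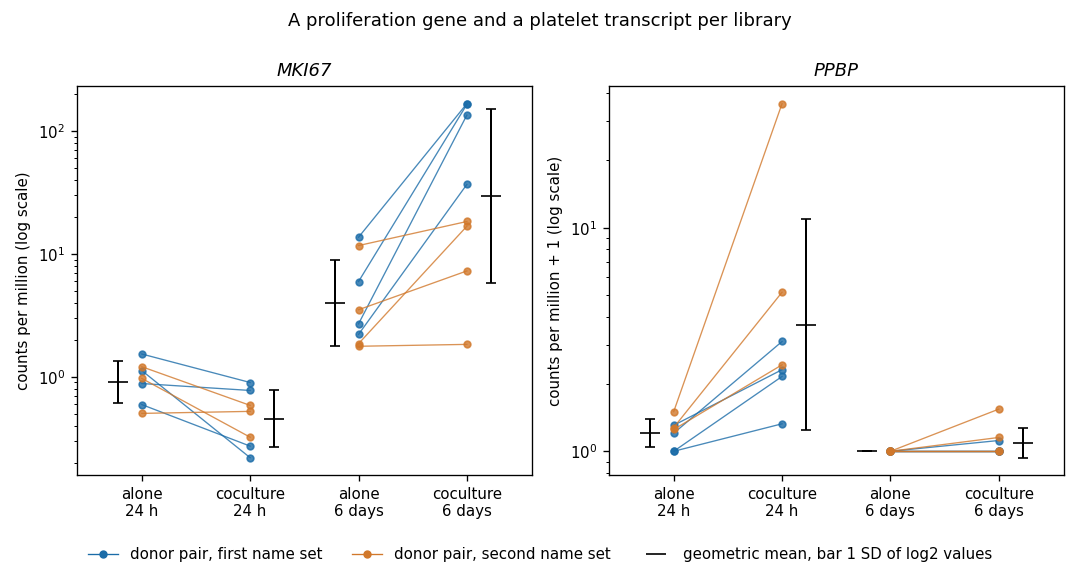
Levels of MKI67 in CPM and of PPBP in CPM + 1, on log axes, for each library at 24 h and 6 days, where lines join donor pairs, colours mark the name sets, and black marks show the geometric mean ± 1 SD of log2 values. At 6 days MKI67 in coculture lay between 36.8 and 167 CPM in the first set and between 1.84 and 18.4 CPM in the second, and at 24 h PPBP in coculture reached 34.9 CPM.

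Across 15576 genes, 730 rose and 544 fell in coculture at 6 days, of which 370 and 163 changed at least 2-fold. With the donor pair as a block, 1521 rose and 1272 fell, and 1243 of the 1274 genes were shared. The first name set alone called 3675 genes and the second 4, or 5100 and 189 with the pair as a block. The count was 794 without replicate 1, 613 without replicate 2, 730 without replicate 3 and 656 without replicate 4.

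The 10 largest rises at 6 days were NEURL1B, KIF20A, DLGAP5, KIF4A, DEPDC1, SLC24A3, ASPM, CKAP2L, CCL18 and RRM2. Their log2 rises ran from 3.89 to 4.90, with adjusted p from 0.000242 to 0.00201 and at least 7 of 8 pairs higher. Of these limma-voom called SLC24A3 and CCL18, with adjusted p of 0.0646 for NEURL1B, 0.105 for KIF20A, 0.0542 for DLGAP5, 0.0596 for KIF4A, 0.104 for DEPDC1, 0.0809 for ASPM, 0.0708 for CKAP2L and 0.109 for RRM2. CCL18, a chemokine gene of alternatively activated macrophages (chromosome 17, 36064280 to 36072032), rose 14.9-fold from 2.70 ± 1.52 to 40.7 ± 51.7 CPM (n = 8 each, log2 3.90 ± 0.58, adjusted p = 0.000242). CCL18 rose by 1.61 in the first name set (adjusted p = 0.00297) and by 4.73 in the second (0.0199). SLC24A3 rose by 4.00 (3.41 without replicate 5).

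TNFSF18, a TNF family ligand gene (chromosome 1, 173039960 to 173050963), fell most at 6 days. It went from 98.7 ± 118 to 1.24 ± 0.824 CPM (n = 8 each; log2 −6.31 ± 0.87, adjusted p = 0.000131, lower in 8 of 8 pairs), and changed by −5.66 without replicate 3. IL1R2, the decoy receptor gene for IL-1, went from 133 ± 126 to 4.50 ± 2.73 CPM (log2 −4.88 ± 0.78, adjusted p = 0.000392, 8 of 8 pairs). FCER2 went from 15.7 ± 11.6 to 0.778 ± 0.486 CPM (−4.32 ± 0.54, 3.71e-05), and ALDH1A2, a retinoic acid synthesis gene, from 74.3 ± 73 to 4.72 ± 4.61 CPM (−3.97 ± 0.67, 0.000675). The other falls were COL1A1 (−5.37), GLDN (−5.05), DKK2 (−4.04), EDN1 (−3.80), SSC5D (−3.53) and COL1A2 (−3.43), with adjusted p from 0.000364 to 0.0492. COL1A1 changed by −3.01 without replicate 4 and −6.05 without replicate 7, and GLDN by −4.01 without replicate 3 and −6.55 without replicate 8. DKK2 was not called without replicate 2 (−3.20, adjusted p = 0.0685) and changed by −5.99 without replicate 8. COL1A2 was not called without replicate 3 (0.0933), 5 (0.0631), 6 (0.0522) or 7 (0.0593), with DESeq2 size factors (0.0501) or without the filter on low counts (0.0824). With limma-voom the falls of IL1R2 (adjusted p = 0.068), COL1A1 (−3.29, 0.0879), GLDN (0.168), DKK2 (0.0574), SSC5D (0.0626) and COL1A2 (0.203) were not called.

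Several immune genes fell at 6 days. TNF went from 11.6 ± 5.70 to 4.68 ± 1.65 CPM (n = 8 each, log2 −1.3 ± 0.28, adjusted p = 0.00309, 7 of 8 pairs lower) and CCL4 from 167 ± 144 to 23.8 ± 14.6 CPM (−2.81 ± 0.51, 0.000991, 8 of 8 pairs). CCL3 changed by −1.24 (0.0173) and was not called without replicate 2 (0.0581), 3 (0.0684) or 4 (0.0742). These were the 3 of 20 NF-kB target genes that fell, with 5 lower and 1 higher adjusted over the list alone and 6 lower under the pair block (list adjusted p = 0.00709, 0.643 with an estimated correlation). F3, the tissue factor gene that starts coagulation, went from 24.3 ± 17.8 to 3.64 ± 2.42 CPM (−2.74 ± 0.56, 0.00228, 7 of 8 pairs), and limma-voom did not call it (−2.33, adjusted p = 0.0756). CD14 went from 1107 ± 352 to 524 ± 181 CPM (−1.08 ± 0.26, 0.00988) and was not called without replicate 2 (−0.97, 0.0506). FCN1 fell from 151 ± 186 to 30.2 ± 16.1 CPM (−2.32, 0.0018). CD80 changed by −1.43 (0.0138), with its call ending without replicate 3 (0.0525), and ITGAL by −1.25 (0.000991). IL10 rose 2.73-fold from 17.9 ± 6.21 to 48.9 ± 15.3 CPM (1.45 ± 0.27, 0.0013, 8 of 8 pairs).

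Lymphocyte markers were lower in coculture at 6 days. Of 17 T and NK cell markers 2 fell with edgeR, with 6 adjusted over the list alone and 11 with the pair as a block (adjusted p = 8.67e-06, 0.643 with an estimated correlation), while limma-voom called none (7 lower at an unadjusted p under 0.05) and DESeq2 6. Of 11 B cell markers 1 fell, FCER2, with 1 adjusted over the list alone and 8 with the pair as a block (adjusted p = 0.00089, 0.643 with an estimated correlation). The T and NK list was below 0 in 7 of 8 pairs and the B cell list in 8 of 8. CD2 changed by −1.64 (adjusted p = 0.0275) and was not called without any of replicates 2, 4, 6, 7 or 8 (0.0532 to 0.075) or with limma-voom (0.0887). PRF1 changed by −2.59 (0.0447), was not called without any of replicates 1, 2, 3, 4, 6, 7 or 8 (0.0548 to 0.194), with limma-voom (0.083) or without the filter on low counts (0.0739), and changed by −1.96 without replicate 2. PAX5 did not pass (−2.56, adjusted p = 0.107) but passed with the pair as a block (−2.20, 0.000773) and with DESeq2 (0.0368).

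Lysosome genes were higher as a list at 6 days as well. Of 22 tested, 5 rose and none fell, with 8 adjusted over the list alone and 11 with the pair as a block (median log2 0.252, adjusted p = 8.31e-06, 0.165 with an estimated correlation). CTSB went from 8842 ± 2923 to 14530 ± 3437 CPM (n = 8 each, adjusted p = 0.00824), and CTSZ rose by 0.65 (0.00483), each in 8 of 8 pairs. Of 23 interferon-stimulated genes 1 rose, HERC5 (1.51, adjusted p = 0.0028), 1 adjusted over the list alone and 2 with the pair as a block (list adjusted p = 7.11e-06, 0.643 with an estimated correlation). Of 10 neutrophil markers 2 rose, with 4 adjusted over the list alone (list adjusted p = 0.0104, 0.256 with an estimated correlation). These were CXCR2 (1.79, 0.00473) and MME (2.86, 0.00549, and 2.20 without replicate 5), of which limma-voom did not call MME (0.0856). Ribosomal protein genes were higher as a list (median 0.178, adjusted p = 0.00142, 0.673 with an estimated correlation). None of 20 was called by edgeR or limma-voom, 6 were higher at an unadjusted p under 0.05, DESeq2 called 1, and 2 rose with the pair as a block. Mitochondrially encoded genes were lower as a list (median −0.17, adjusted p = 0.0055, 0.643 with an estimated correlation), where edgeR and limma-voom called none of 13, 5 were lower at an unadjusted p under 0.05, DESeq2 called 2, and 3 fell with the pair as a block.

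The remaining lists did not pass at 6 days, although the macrophage markers (adjusted p = 0.105) passed with the pair as a block (0.0132). Chemokine genes split, with 3 higher and 2 lower of 16, or 3 and 6 adjusted over the list alone (adjusted p = 0.919), and CCL23 rose (2.25, 0.002). Alternative activation genes had 4 higher and 1 lower of 15, or 4 and 3 adjusted over the list alone (adjusted p = 0.424), and TGM2 rose (1.84, 0.0112). Adjusted p was 0.869 for platelet, 0.919 for dendritic cell and 0.496 for monocyte markers, 0.389 for antigen presentation, 0.163 for inflammasome and 0.828 for complement genes. It was 0.919 for both NRF2 targets and reactive oxygen genes, 0.523 for oxidative phosphorylation, glycolysis and coagulation, and 0.389 for lipid uptake. It was 0.88 for adhesion and ER stress, and 0.424 for matrix proteolysis, TGF-beta response and heat shock genes. Median, mean and test differed in sign for the dendritic (−0.263, 0.178, down), chemokine (0.067, −0.059, up), coagulation (0.344, −0.037, up), alternative activation (0.482, −0.002, up), adhesion (−0.015, 0.064, up), NRF2 (0.061, −0.012, down) and ER stress lists (0.051, 0.156, down).

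Named genes of these lists also changed at 6 days. ITGB3, a platelet integrin gene, rose by 3.43 (adjusted p = 0.00179, and 2.33 without replicate 5), while NRGN, another platelet marker, changed by −2.27 (0.0032) and was not called with limma-voom (0.0863). CDKN1C rose by 2.03 (0.00225), ADAM8 by 2.45 (0.00329) and F11R by 0.80 (0.0013). PROCR rose by 2.46 (0.0148) and was not called without replicate 5 (1.88, 0.0692) or with limma-voom (1.60, 0.31). FTL rose by 0.56 (0.0185) and was not called without replicate 2 (0.0872), 3 (0.0579) or 4 (0.0663), without the filter on low counts (0.0509) or with only the 2 groups compared (0.0539). GCLC changed by −0.67 (0.00228), SMAD6 by −1.23 (0.00549) and ID1 by −2.70 (0.00108, and −3.44 without replicate 5). TIMP1 changed by −1.0 (0.0398) and was not called without any of replicates 1, 2, 3, 4, 7 or 8 (0.0617 to 0.122), without the filter (0.0613) or with only the 2 groups compared (0.0799). Of the fixed panel, HLA-DRA (−0.60, adjusted p = 0.337), FCGR3A (0.73, 0.276), HMOX1 (0.62, 0.144), TXNIP (0.49, 0.177) and MRC1 (0.56, 0.452) did not pass but passed with the pair as a block (0.0464, 0.00105, 0.0112, 0.022 and 0.0237). HMOX1 also passed without replicate 6 (0.85, 0.0251). In the first name set alone HMOX1 (1.37, adjusted p = 0.000124), TXNIP (0.87, 0.00087), MRC1 (1.41, 0.0168), CYBB (0.87, 0.00304), CCL2 (−1.59, 0.0389), THBS1 (1.15, 0.0315) and CD163 (1.87, 0.000528) passed. CD36, NQO1, SOD2, CYBB, IL1B, CXCL8, CCL2, THBS1 and CD163 did not pass over all libraries, with adjusted p from 0.634 to 0.99. IL6 was too low to test, at a ratio of 2.185 with a counting interval of 1.043 to 4.9.

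**Figure D3:**
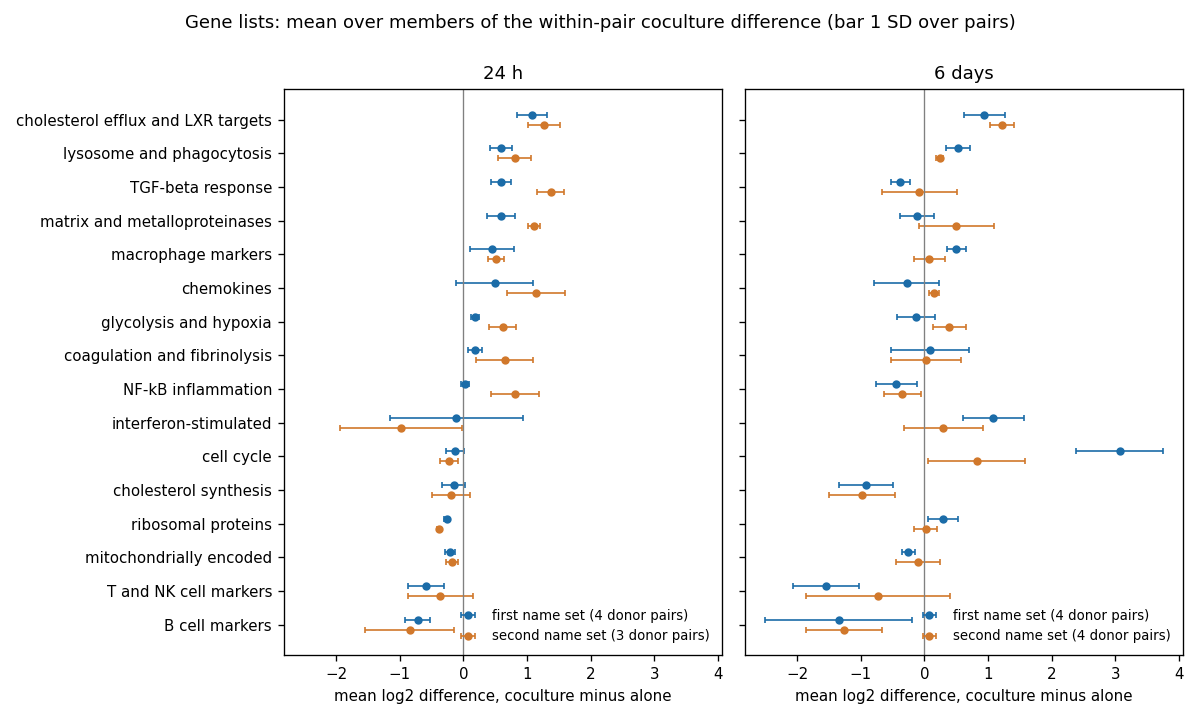
Mean log2 difference between coculture and alone within donor pairs for 16 gene lists at 24 h and 6 days, where points are means over the pairs of a name set and bars are ± 1 SD over pairs. The cell cycle list at 6 days stood at 3.07 in the first set and 0.82 in the second, while the cholesterol synthesis list stood at −0.92 and −0.98.

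Platelet transcripts were scarce in both arms. The share of counts in 26 platelet marker genes at 24 h was 0.0191 ± 0.0044% alone and 0.0133 ± 0.0029% in coculture (n = 7 each, difference −0.00586, exact two-sided permutation p = 0.0128, lower in 6 of 7 pairs). At 6 days it was 0.0371 ± 0.0177% and 0.0192 ± 0.00519% (n = 8 each, difference −0.018, exact two-sided permutation p = 0.0149, lower in 8 of 8 pairs). SPARC was in that list and made up 14.1 to 50.4% of its counts in monocytes alone at 24 h and 56.6 to 92% at 6 days. Without SPARC the shares were 0.0116% and 0.0111% at 24 h (exact permutation p = 0.712, lower in 6 of 7 pairs) and 0.00726% and 0.00607% at 6 days (exact permutation p = 0.402, lower in 4 of 8 pairs), so that neither difference passed. The 6 core platelet transcripts taken alone went the other way, with 0.383 CPM alone and 6.75 CPM in coculture at 24 h (higher in 7 of 7 pairs) and 0.12 and 0.28 CPM at 6 days. Cocultured replicate 7 at 24 h held 803 of the 1069 core counts, and without that replicate the 24 h means were 0.289 and 2.35 CPM (higher in 6 of 6 pairs). PF4, a platelet chemokine gene, had 0 counts in monocytes alone at 24 h and 96 in coculture, at least 30.8-fold higher on counts pooled over each group against a floor of 3 counts, or 14-fold without replicate 7. Only 3 of 7 cocultured libraries had PF4 counts. PPBP at 6 days had 0 counts alone and 15 in coculture, at least 4.62-fold higher on pooled counts or 1.51-fold without replicate 8, and did not pass (adjusted p = 0.229, higher in 3 of 8 pairs). At 6 days PF4 was near the floor in both arms.

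The effects of coculture at the 2 times were compared next, by testing the 6-day effect minus the 24 h effect. SMAD6, an inhibitor gene of BMP signalling, changed by 1.51 at 24 h and −1.23 at 6 days (difference −2.74 ± 0.41, adjusted p = 0.00164). ID3 changed by 2.27 and −0.79 (−3.06 ± 0.47, 0.00173), and PLAU by 2.56 and 0.34 (−2.21 ± 0.38, 0.00892). RASGRP3 and MEF2A also had lower effects at 6 days (−1.98, 0.00164 and −0.86, 0.00903). CCNB2, a mitotic cyclin gene, changed by −0.99 and 2.11 (3.10 ± 0.61, 0.0182) and was not called with limma-voom (2.54, 0.113), and ETFDH, AGPAT5, RPL4 and PIGX had differences of 0.66 to 1.17 (adjusted p from 0.0153 to 0.0193). Across all genes, 85 differences were positive and 131 negative, against 466 and 588 with the pair as a block (205 of 216 shared). The first name set alone called 1128 and the second 4.

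Lists also differed between the times, although none of the 10 calls passed with an estimated correlation. Cell cycle genes (7 of 20, adjusted p = 4.57e-18, 0.197 with an estimated correlation) and ribosomal protein genes (2 of 20, 8.94e-19, 0.197) had higher effects at 6 days, 16 and 20 adjusted over the list alone. The interferon (3.48e-12, 0.213), inflammasome (0.00584, 0.368) and oxidative phosphorylation lists (0.033, 0.825) were higher too. TGF-beta response genes (4 of 17, 9 adjusted over the list alone, 2.26e-13, 0.111) and cholesterol synthesis genes (2 of 21, 12 adjusted over the list alone, 1.95e-13, 0.213) had lower effects at 6 days. So did the NF-kB (4.94e-05, 0.464), lysosome (0.0218, 0.593) and matrix proteolysis lists (0.033, 0.593). With the pair as a block, 9 cell cycle, 17 ribosomal protein, 8 TGF-beta response, 11 cholesterol synthesis and 6 NF-kB target genes differed. With limma-voom 0 of 20 cell cycle genes differed (4 higher at an unadjusted p under 0.05), against 14 with DESeq2, and 0 of 20 NF-kB target genes (7 lower at an unadjusted p under 0.05), against 1 with edgeR and 2 with DESeq2. For ribosomal protein, TGF-beta response and cholesterol synthesis genes limma-voom called 1, 4 and 3, and DESeq2 15, 9 and 7. The T and NK cell (adjusted p = 0.0611), B cell (0.197) and monocyte marker lists (0.112) did not pass but passed with that block (0.00171, 0.0344 and 0.0244). Rises at both times were shared by 109 genes against 25 in independent lists, and falls by 30 against 6. Another 3 genes rose at 24 h and fell at 6 days, and 1 did the opposite. Across genes, which are not independent replicates, the effects at the 2 times correlated at r = 0.281 and rho = 0.215, in libraries of largely the same donors.

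Culture time changed more genes than platelets did. In monocytes alone SPP1, the osteopontin gene of tissue macrophages (chromosome 4, 87975650 to 87983426), rose 673-fold from 72.8 ± 73.3 CPM at 24 h (n = 7) to 49030 ± 38280 CPM at 6 days (n = 8; log2 9.40 ± 1.12, adjusted p = 7.71e-08). CCR2, the CCL2 receptor gene (chromosome 3, 46353734 to 46360928), went from 326 ± 89.4 to 1.80 ± 2.77 CPM (−7.49 ± 0.65, 3.28e-10), and SUCNR1 from 1.13 ± 0.597 to 129 ± 59.1 CPM (6.83 ± 0.48, 1.33e-11). The other largest rises were HPGDS, AFAP1L1, TSPAN12, BCAR1, GPD1 and HTR2B, at 7.00 to 8.06 with adjusted p from 5.7e-10 to 3.3e-06. NMRK2 was at 0 counts at 24 h and at 3.55 ± 2.99 CPM at 6 days, at least 140.7-fold higher (4.13e-05), and RND3 had a ratio of 307.3 with a counting interval of 104.9 to 1492. The other largest falls were CCL24, CD300E, S100A12, THBS1, FCER1A, CX3CR1, CORIN, NRG1 and EREG, at −7.39 to −5.29 with adjusted p from 3.19e-10 to 2.23e-05. Across all genes 4403 rose and 4032 fell with time, and the first and second name sets alone called 8131 and 4689. FCER1A did not pass within the second set (−3.70, adjusted p = 0.0687).

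Macrophage markers rose and monocyte markers fell with time in monocytes alone. Of 22 macrophage markers 17 rose and 1 fell (median 2.89, adjusted p = 1.43e-08, 0.0235 with an estimated correlation), and of 18 monocyte markers 11 fell and none rose (−1.93, 1.57e-05, 0.0264). The same numbers held adjusted over the list alone. Lysosome genes (15 of 22 rose, adjusted p = 4.03e-11, 0.0255) and lipid uptake genes (12 of 20 rose and 3 fell, 0.000328, 0.0264) also passed both ways. All 24 oxidative phosphorylation genes rose (median 0.73, 8.65e-12, 0.294 with an estimated correlation). Efflux genes were higher (9 of 14 rose and 1 fell, 0.00801, 0.379), and dendritic cell markers (8 of 12 fell, 0.0367, 0.379), inflammasome genes (8 of 13 fell and 2 rose, 0.0405, 0.524) and NF-kB target genes (11 of 20 fell and 3 rose, 0.0476, 0.909) were lower. Cholesterol synthesis (0.0808), heat shock (0.0519) and cell cycle genes (0.0875) did not pass but passed with the donor as a block (0.024, 0.0394 and 0.047).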

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

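The tests of lymphocyte markers, of the cell cycle list between name sets and of platelet RNA were chosen after those results were seen, and the tests of other splits and of the name sets were planned.

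In 28 of 344 groups of libraries 1 library stood apart from the others, where a gap to its nearest neighbour took up an unusual share of the group's range. Genes were checked on the log2(CPM + 1) scale. Total counts, mitochondrial and platelet shares and the core platelet transcripts were checked without logs, so their shares of range are not comparable with those of genes. Chance gives about 1 in 20 groups, or 17.2 here. Cocultured replicate 7 at 24 h stood apart in 8 of these. It was highest for ACKR3 (share of range 0.571, 211 CPM), PPBP (0.589, 34.9 CPM), SLC16A10 (0.586, 216 CPM), CXCL1 (0.661, 109 CPM), CD14 (0.701, 3651 CPM), CD163 (0.739, 1825 CPM) and the core platelet transcripts (0.832, 33.1 CPM), and lowest for APOC1 (0.574, 65.8 CPM). Replicate 7 of monocytes alone at 24 h was highest for CXCL5 (0.734), STEAP4 (0.677) and CXCL1 (0.676), and replicates 5 and 6 stood apart for MAFG (0.664), BCAR1 (0.657), WNT5A (0.651) and ANGPT1 (0.617). Cocultured replicate 6 at 24 h stood apart for CYBB (0.589). At 6 days, cocultured replicate 5 stood apart for ID1 (0.567), CYBB (0.631) and CD163 (0.678), and cocultured replicate 8 for GLDN (0.845), DKK2 (0.676) and PPBP (0.672). Monocytes alone at 6 days stood apart for APOC1 (0.59, replicate 7), ADAM8 and NRG1 (0.59 and 0.659, replicate 8), MYLIP (0.63, replicate 1), COL1A1 (0.614, replicate 4) and total counts (0.668, replicate 2, the lowest at 10.5 M).

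For 24 of 122 named genes the coculture effect differed between the times by an adjusted p under the threshold of edgeR. Of all 15576 genes tested, 216 did. The named genes include 10 taken for their small p in this same test, and others were taken for a large effect at 1 time. The count among named genes therefore does not show how common such differences are. Differences of 6 days minus 24 h were negative for IL1R2 (−5.35), ACKR3 (−4.57), CCL2 (−4.48), SLC16A10 (−4.12), ALDH1A2 (−3.98), LTBP2 (−3.07), ID3 (−3.06), CCL4 (−3.04), SMAD6 (−2.74), CABLES1 (−2.51), PLAU (−2.21), RASGRP3 (−1.98), MEF2A (−0.86), MVD (−0.78) and MAFG (−0.64). They were positive for MKI67 (4.53), BIRC5 (3.55), CENPF (3.37), CCNB2 (3.10), CCL23 (2.51), AGPAT5 (1.17), PIGX (0.96), ETFDH (0.66) and RPL4 (0.64). Adjusted p ran from 0.00164 to 0.0453.

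Cell cycle genes such as MKI67 rose in coculture at 6 days. Dividing lymphocytes carried through the selection were tested as a source, and the T and NK cell and B cell lists had medians of −1.25 and −2.10 in the same comparison, which argues against them. A difference between the name sets may add to it, as the list rose more in the first set, with an exact permutation p of 0.0286, the smallest possible, but 0.0985 when adjusted over 31 lists. Donor and batch differences cannot be told apart there, because each donor's pair lies within 1 name set. Division of the monocytes themselves may therefore explain the rise in part of the donors, as a hypothesis found and weighed on the same libraries.

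Platelet RNA carried into the libraries was tested as the source of the rises, taking the gain of PPBP as a guide, since it is among the most abundant platelet messages. At 24 h, 409 of 533 risen genes off the platelet list, or 76.7%, gained more CPM than PPBP did (median gain 18 against 6.26 CPM). The PPBP gain rests largely on replicate 7, and without it 491 of the 533, or 92.1%, gained more (median 16.1 against 1.57 CPM). Leaving out that library lowers the PPBP gain to be exceeded, so the higher percentage is no added support. At 6 days 100% of 729 did (median 6.49 against 0.102 CPM). PPBP had only 15 counts in coculture there, and nearly any called gene exceeds so small a gain. The 6-day result therefore rests on the scarcity of PPBP and not on the percentage. The values over all pairs argue against platelet RNA for the 409 genes at 24 h and for those at 6 days. For the remainder at 24 h it could still contribute. A change in the monocytes' own transcripts stays open as the biological explanation.

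Coculture called 3675 genes at 6 days in the first name set and 4 in the second, or 5100 and 189 with the donor pair as a block. The within-pair effect differed between the sets for 756 genes by limma, and the highest of the other splits of the 8 pairs into 4 and 4 gave 0. The real split was the only 1 of 35 to give as many, the strongest result that 35 splits allow. This makes chance less likely but does not exclude it. At 24 h the within-pair effect differed between the sets for 0 genes by limma, with 2274 at an unadjusted p under 0.05. Chance cannot be excluded there either, as the highest other split gave 1. Between the sets, monocytes alone at 6 days differed for 3 genes (3860 at an unadjusted p under 0.05, highest other split 3) and cocultured ones for 0 by limma (1512 at an unadjusted p under 0.05, highest other split 3). The monocytes alone, rather than the cocultured ones, might thus differ between the sets, but 3 against 0 genes are too few to say, and donor and batch cannot be told apart.

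By other splits of the same libraries, chance is an unlikely source of the counts of changed genes between arms and times. At 24 h the real split called 705 genes, the highest of the others drawn 516, and the highest of the other splits that part every pair 175. At 6 days these were 1274, 495 and 826. For time they were 8435, 5401 and 7891 in monocytes alone, and 9021, 5868 and 8428 in cocultured monocytes. For the difference between the times, limma on within-pair differences called 943 genes and the highest other split 1. In each of these cases 1 split, the real one, gave as many genes, of 100 drawn or of 64 that part every pair at 24 h. For the 6-day effect between the name sets it was 1 of 35, with the limit given above. Between the sets 35 of 35 splits gave as many genes for the 24 h effect and for cocultured monocytes at 6 days, and 2 of 35 for monocytes alone.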

How the results depend on the processing

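Tests within the name sets for the difference between times and for time itself, name sets with the replicate block, limma on within-pair differences, the omission of 2 pairs and that of SPARC from the platelet list were chosen after results were seen. The cause of each change below was not tested, except where fewer libraries or more genes tested are its construction.

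The counts of changed genes at 24 h, at 6 days and with time in monocytes alone stayed within 1.5 times with DESeq2 size factors (696, 1252 and 8479), no filter on low counts (474, 896 and 8438), the DESeq2 Wald test (1008, 1680 and 8680) and limma-voom (628, 980 and 8320). For time in cocultured monocytes they were 9068, 9427, 9222 and 8933. The coculture counts also did with only the 2 groups compared (581 and 995), the name set as a term (874 and 1510) and platelet genes removed (702 and 1272). With the replicate block they moved from 705 to 1923 and from 1274 to 2793. The count for the difference between times, 216, was 212 with size factors, 53 without the filter (35342 genes tested), 652 with DESeq2, 1.0e+02 with limma-voom (32 positive and 71 negative), 1054 with the replicate block and 943 with limma on within-pair differences. Leaving out 1 replicate gave 278 to 668 genes at 24 h and 613 to 1565 at 6 days.

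Within name sets, with fewer libraries, the first and second gave 78 and 281 genes at 24 h, 3675 and 4 at 6 days, 1128 and 4 for the difference between times and 8131 and 4689 for time in monocytes alone. With the replicate block within each set they gave 497 and 2131 at 24 h and 5100 and 189 at 6 days. Without the 2 pairs richest in B cell transcripts the 6-day count was 823, and 55 of the 58 named genes tested kept their call. Gene lists called went from 12 to 3 at 24 h and from 11 to 2 at 6 days with a correlation estimated per list, and to 7 and 5 with fry. They were 15 and 12 with the replicate block, 16 and 11 without the filter, and 12 and 11 with size factors.

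The platelet transcript share was higher instead of lower in coculture when the 6 core transcripts were taken, by 0.000637 at 24 h (exact permutation p = 0.00233) and by 1.6e-05 at 6 days (exact permutation p = 0.0774). Without SPARC the difference was −0.000532 at 24 h (exact permutation p = 0.712) and −0.0012 at 6 days (exact permutation p = 0.402). Without 1 replicate the difference ran from −0.00703 to −0.00477 at 24 h and from −0.0204 to −0.0144 at 6 days.

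No named gene called in the coculture comparisons, the difference between times or time in monocytes alone changed sign under any alternative run. Of those called, 54 at 24 h and 59 at 6 days, 53 and 56 could be tested in every omission of 1 replicate, and 36 and 47 kept their call in each. PPBP at 24 h and KIF4A, DEPDC1 and COL1A2 at 6 days were too low to test in some. Of the 54 and 59, limma-voom kept 47 and 37, the losses being named beside each result. DESeq2 kept 53 and 59, losing CXCL5 at 24 h (1.39). The first name set kept 16 of 52 tested and 55 of 59, and the second 24 of 54 and 1 of 56. The replicate block kept all of them, added SOD2 and MRC1 at 24 h and PAX5, HLA-DRA, FCGR3A, HMOX1, TXNIP and MRC1 at 6 days, and added the NF-kB, T and NK and B cell lists at 24 h and the macrophage list at 6 days. Of the other lists it changed 3 for the difference between times, 3 for time in monocytes alone and 3 in cocultured ones, whose values stand beside those results. It changed no other call. Calls gained with the block within a set were MRC1 in the first at 24 h (0.94), USP18 (−2.50), HMOX1 (0.87), SOD2 (0.82), MRC1 (1.17) and CD163 (0.93) in the second at 24 h, and in the first at 6 days PAX5 (−2.43), FCGR3A (0.62) and NQO1 (0.48) besides those gained there without it.

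Panel genes that did not pass crossed 0 in places. With the replicate block these were CD36 (−0.06 at 24 h, 0.00 at 6 days) and, at 6 days, NQO1 (−0.05), CYBB (0.14), CXCL8 (−0.16) and THBS1 (0.17). With limma-voom they were CD36 (−0.06 and 0.00), NQO1 (−0.07), CYBB (0.16), CXCL8 (−0.19) and THBS1 (0.39). CD36 was 0.00 at 24 h with only the 2 groups compared, and CYBB 0.15 at 6 days with the set term. In the first set these were CD14 (−0.21) and CXCL8 (−0.16) at 24 h, and SOD2 (−0.02), CXCL8 (−0.10), CYBB (0.87, adjusted p = 0.00304) and THBS1 (1.15, 0.0315) at 6 days. With the block in that set they were CD14 (−0.21), CXCL8 (−0.18), and at 6 days SOD2 (−0.03), CYBB (0.93), CXCL8 (−0.33) and THBS1 (1.12). In the second set they were CD36 (−0.06) and F3 (0.00) at 24 h and NQO1 (−0.48), CCL2 (0.60) and CD163 (−0.19) at 6 days. With the block there they were CD36 (−0.21 and −0.01), NQO1 (−0.61), CCL2 (0.07) and CD163 (−0.41). Without the 2 pairs richest in B cell transcripts CD36 was −0.04 and CXCL8 −0.01. Leaving out 1 replicate gave lowest and highest values of −0.08 and 0.09 for CD36 at 24 h, and at 6 days of −0.07 and 0.13 for CD36, −0.07 and 0.10 for SOD2, −0.13 and 0.11 for CYBB, and −0.03 and 0.17 for CXCL8.

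In simulated counts 8% of 1.5-fold changes were recovered at 24 h and 4% at 6 days, against 68% and 72% of 2-fold changes. The simulated spread was not that of each gene in the data, so these rates are only a rough guide. Genes below the filter, such as IL6 and PF4, were not tested with it.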

Other observations

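The test of the cholesterol lists across pairs was chosen after the lists' results were seen, and the tests of time against coculture were planned.

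Cocultured monocytes changed with time much as monocytes alone did. Between 24 h and 6 days 4600 genes rose and 4421 fell in them, and 3492 rises and 3243 falls were shared with monocytes alone, against 1300.3 and 1144.4 in independent lists. The 2 time comparisons have no library in common but use the same donors, so the numbers for independent lists leave out what shared donors add. In coculture 19 of 20 cell cycle genes rose with time (median log2 4.43, adjusted p = 1.97e-06, 0.435 with an estimated correlation), against 10 of 20, with 1 falling, in monocytes alone (list adjusted p = 0.0875). Interferon-stimulated genes also rose (18 of 23, with 2 falling, median 1.43, 0.00204, 0.614), while 15 of 17 TGF-beta response genes fell and 1 rose (1.97e-06, 0.221) and 15 of 20 NF-kB target genes fell and none rose (0.000123, 0.435). All 24 oxidative phosphorylation genes rose (5.3e-14, 0.197), as did 18 of 20 ribosomal protein genes (1.97e-06, 0.435), 16 of 22 macrophage markers (1 fell, 1.93e-06, 0.0533), 16 of 22 lysosome genes (1 fell, 1.57e-06, 0.0881), 14 of 20 lipid uptake genes (4 fell, 0.000466, 0.0533) and 8 of 14 efflux genes (3 fell, 0.0279, 0.435). Falls were seen for 14 of 18 monocyte markers (1 rose, 2.46e-06, 0.0533), 8 of 12 dendritic cell markers (0.0263, 0.388) and 13 of 20 heat shock genes (5 rose, 0.0279, 0.435). None of these 13 lists passed with an estimated correlation. With the donor as a block the efflux genes no longer passed (adjusted p = 0.0626), while the T and NK cell (0.00982, from 0.0788) and B cell marker lists (0.0161, from 0.233) did. Haemoglobin transcripts gave 1 tested erythroid marker, HBA2, with a median change of −0.932 at 24 h and 1.292 at 6 days.

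A first hypothesis was that coculture at 24 h moves genes the way time in culture does. Coculture effects at 24 h in 1 name set were correlated with time effects in monocytes alone from the other, so that no donor was shared. Across genes, which are not independent replicates, r was 0.21 for the first set's coculture effects and 0.089 for the second's (rho 0.148 and 0.078). For coculture effects at 6 days r was 0.124 and 0.239 (rho 0.073 and 0.29). Coculture effects of the 2 sets correlated with each other at 0.50 at 24 h and 0.362 at 6 days (rho 0.485 and 0.242). The 24 h values may fit a small shared direction but are too low to say so.

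A second hypothesis was that a shared sterol response lowers synthesis and raises efflux genes in the same donors. Over the 8 pairs at 6 days, the effects on the 2 lists correlated at r = −0.31 (exact permutation p = 0.433) and rho = −0.71 (exact permutation p = 0.0576), as 1 relation tested. Without the 2 pairs farthest from the median effect on the synthesis list, r was −0.73 over 6 pairs, a value for which no p was computed. A common sterol signal could lie behind both lists, but 8 pairs do not decide it.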
